A study of Mus musculus with 4 samples.

How the data were processed

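The 4 samples were 3T3-L1 cells, a mouse preadipocyte line that turns into fat-storing adipocytes when given an induction mixture. Per the labels, the mixture held 0.5 mM isobutylmethylxanthine, 1 µM dexamethasone and 1 µg/ml insulin and was applied for 48 hours, and 2 samples also received 13.47 µM berberine, a plant alkaloid. Groups were taken from the sample titles, with which the source names and descriptions go together. The treatment protocol text in the labels is identical for all samples and mentions berberine for the controls too, so it was not used to assign groups. Nothing in the labels says that the samples came from separate cultures or days, so p-values measure only the spread between these arrays, which may be technical. No batch is named in the labels, so no batch term could be fitted, and whether the groups were handled apart is not known.

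RNA was labelled with Cy5 and hybridised to 1-colour arrays, 1 per sample, per the labels' protocols. The deposited values are linear probe intensities in whole numbers, a few of them below 0. The scanner, the background correction and any scaling that the authors applied are not given in the sources used here, so the zero point and scale of the intensity values stay unknown. The median deposited intensity was 423 and 350 on the control arrays and 237 and 280 on the berberine arrays. The 4 medians differed by 0.84 on the log2 scale, more than the limit of 0.5 set before the data were examined, and quantile normalization between arrays (limma 3.58.1, R 4.3.3) was therefore the main setting. Precision is limited by the number of arrays.

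The table held 26423 probes, of which 20377 had 1 gene symbol, 0 had several and 6046 were unnamed here. Of the named probes, 18213 matched a current mouse symbol apart from case, 2126 were matched through an older symbol and 38 kept the platform's symbol. The 15 probes at or under 0 on any array were left out, and 26408 were fitted on log2 intensity with no pseudocount. A gene with several probes was represented by the probe with the highest mean over all arrays, which gave 17734 genes.

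Berberine was compared with control by a limma fit (lmFit, eBayes) for each probe, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Exact permutation of 2 against 2 arrays cannot give a two-sided p under 0.33, so every p rests on limma's pooled spread, with 2 residual and 2.89 prior degrees of freedom. That spread is assumed equal in both groups. Among probes above log2 10 in control, the median absolute difference between the arrays of a group was 0.26 for control and 0.088 for berberine. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members, and again with an estimated correlation, where camera's p uses only the 2 residual degrees of freedom. The 29 pathway lists and 8 lists of cell type markers were fixed before the data were examined, as were the test, the normalization rule and the rule for naming genes. That rule took a set of fixed genes, of which 11 were analysed here, the 8 largest rises and 8 largest falls among called genes above the median level of all probes with both arrays of one group above both of the other, and up to 4 members with the smallest p for each list past the threshold and for 7 lists chosen in advance.

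Several choices were made after the data were seen. A floor was set at the 25th percentile of an array's normalized values, an intensity of 95.8. Where the dimmer group lay under it, the fold is given as "at least", the brighter group's mean over the floor, and where both groups lay under it no fold is given. Probes that changed at least 8-fold, and pairs of probes of one gene that were both above log2 10 in control, were examined as classes. A second definition of such pairs, above log2 10 in either group, was also looked at. Each list was compared with 10000 random lists of the same size, matched on control level in 20 bins. Genes are not independent replicates, so the p-values from random lists are too small where members move together. Scaling on the 75th percentile, and a fit without the probes that changed at least 8-fold, were added as well.

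The fit was tested on simulated arrays with 26408 probes and known changes. Several forms of simulated spread were tried, and recovery depended on the form. With 200 changed probes, 0% to 54% of 2-fold and 51% to 97% of 4-fold changes were recovered, and 0% to 9.09% of the calls were false. With 10000 changed probes, closer to the number called here, 81.9% to 93.9% of 2-fold and 95.9% to 99.4% of 4-fold changes were recovered, but 9.04% to 13.7% of the calls were false, above the nominal 5%. When the true array offsets were removed in place of quantile normalization, the false share was 2.92% to 3.19%, so in the simulation the excess came from quantile normalization. Adjusted p-values of small changes can therefore be too low. The planted rises and falls were equal in number and size and lay at random probes. In the data, large changes were mostly falls at probes bright in control, so these recovery and false shares may not carry over. Camera gave p under 0.05 for 3% of 200 random unchanged lists. The comparison with matched random lists gave it for 5.25% of 400 random lists. A wrong divisor in an earlier run of that simulation was corrected, and the p-values of the lists did not depend on it. The matched p-values shift a little with the random draw. Both checks of the list tests used genes drawn at random, the matched one from its own reference genes. Neither tests lists whose members move together.

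Alternatives tried were the deposited values with no normalization, centring on the median, the replicate number as a block, an intensity trend with a robust prior, each array left out in turn, log2(value + 16), filters on dim probes, other thresholds, probes averaged per gene, and camera on ranks. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the probe pairs, the random lists and the plots.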

Results

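Gene expression was measured on arrays in 3T3-L1 preadipocytes given the adipogenic induction mixture for 48 hours, in 2 samples without berberine (control) and 2 with 13.47 µM berberine. The comparison asks how berberine changed expression during the induced differentiation. Log2 intensities of the 2 control arrays correlated across probes at r = 0.989 and those of the berberine arrays at r = 0.994, against 0.912 to 0.914 between groups. Values below are quantile-normalized log2 intensities, fold changes are berberine minus control, and adjusted p-values are from limma.

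Berberine samples differed from controls at a large share of the genes measured, with adipocyte genes among the strongest falls. Of 26408 probes, 7164 were higher and 4674 lower with berberine. By 1 representative probe per gene, 5321 of 17734 genes were higher and 3219 lower. At least a 2-fold change in addition was met by 2863 higher and 2943 lower probes. The direction depended on scaling, because the median log2 change of all probes was 0.17 after quantile normalization, -0.05 in the deposited values, 0.52 after centring on the median and 0.26 after scaling on the 75th percentile. Lower probes made up 39.5% of the calls in the first case, 64.2% in the deposited values (2396 higher, 4291 lower) and 23.6% after centring (10694 higher, 3311 lower). Without berberine replicate 1 or 2, 4339 and 4621 probes passed in place of 11838.

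Large changes ran mostly one way and were often specific to a probe. At least 8-fold falls were seen at 771 probes and rises of that size at 29. Of 8966 probes above log2 10 in control, 7.38% fell at least 8-fold, with 5.23% to 9.32% in each log2 level bin above 10. Among 524 genes with 2 such probes, the fold changes of the 2 probes correlated across genes at r = 0.17 (Spearman's rho 0.20). Genes are not independent replicates. In 111 of these genes at least 1 probe fell 8-fold or more, and in 35 of the 111 the other probe fell at least 2-fold. Among 1183 genes with several probes and a called representative, 272 had another probe called in the opposite direction. Of the genes named by the rule, only Dlk1, Cox6a2, Pmvk and Birc5 had another probe. The folds of the others rest on 1 probe each and could not be checked in this way. Some other list members had 2 probes above log2 10 in control, and these went both ways. Lpin1 (-3.26 and -5.92 on log2), Rxra (-0.76 and -0.90) and Acta2 (1.22 and 1.68) moved alike at both. Cd36 fell at 1 probe (-3.39) and did not pass at the other (-0.45). Slc25a20 (-1.78 and 0.69), Ctsb (-0.81 and 1.21) and Hes1 (0.81 and -0.98) were called both ways. List counts use the representative probe alone. For the lists past camera and for cell cycle, stress response and inhibitor genes, the number of 8-fold falls is therefore given beside the mean number in random lists matched on control level.

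**Figure D1:**
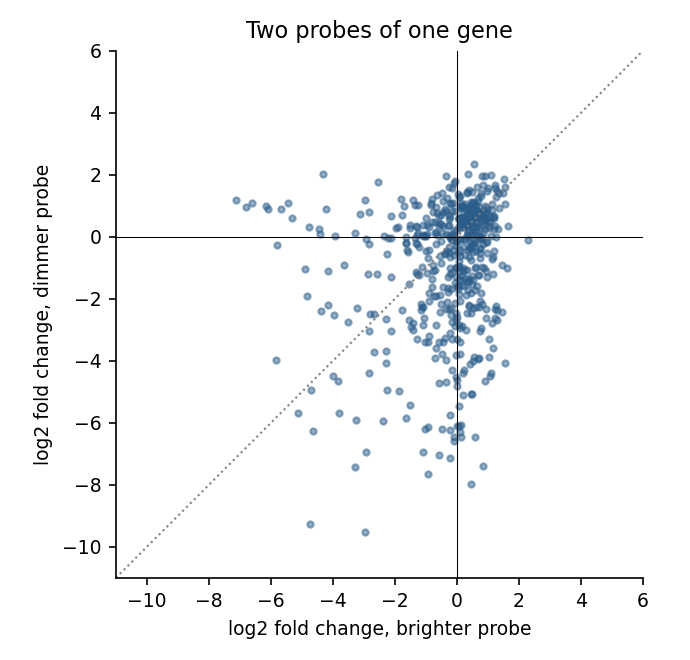
Log2 fold change of the brighter probe (x axis) and the dimmer probe (y axis) of 524 genes with 2 probes above log2 10 in control, 1 point per gene, with the line of equality dotted. The points scatter along both axes (r = 0.17), with many genes at which 1 probe fell and the other did not.

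Genes of mature adipocytes were lower with berberine. Adipoq, which encodes the hormone adiponectin, was at 17.51 ± 0.065 (SD, n = 2) in control and 10.54 ± 0.042 with berberine, a 125-fold fall (log2 change -6.97, SE 0.12, adjusted p = 5.77e-05). Fabp4, a fatty acid binding protein of adipocytes, fell 7.06-fold, from 17.59 to 14.77. Cfd, the secreted protease adipsin, fell at least 717-fold to below the floor, Cidec, a lipid droplet protein, fell 848-fold and Car3, a carbonic anhydrase, 119-fold. Of 27 measured mature adipocyte markers, 19 fell, 2 rose and 6 did not pass (20 fell and 2 rose adjusted over the list alone), with a median log2 change of -2.82 (-2.76, -2.19 and -2.45 in the deposited values, after centring and after scaling on the 75th percentile). Camera gave adjusted p = 2.26e-10, and adjusted p = 0.373 with an estimated correlation. At least 8-fold falls were counted at 13 members, against 1.41 in matched random lists. The Lpl probe lay under the floor in both groups, so this array gives no fold for lipoprotein lipase.

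Adipogenic transcription factors were lower as a list, with members moving both ways. Cebpa, a late factor of the adipogenic cascade, fell 6.73-fold (log2 change -2.75, SE 0.13, adjusted p = 0.000215), and Cebpd, an early one, fell 2.30-fold (adjusted p = 0.00438), a call lost without either berberine array. The early factor Cebpb was at 14.79 ± 0.46 in control and 14.42 ± 0.024 with berberine (n = 2 each), a log2 change of -0.37 that did not pass (adjusted p = 0.270), passed without control replicate 2 (adjusted p = 0.0277) and was 0.41 after centring and 0.15 after scaling on the 75th percentile. Nr1h3, the liver X receptor alpha, fell 5.46-fold, Zfp423, a factor of preadipocyte commitment, 3.70-fold, and Stat5a, a signal transducer, at least 17.8-fold. Srebf1, a regulator of lipid synthesis genes, had a log2 change of -0.47 that did not pass (adjusted p = 0.0587) but did in the deposited values (adjusted p = 0.0368) and without control replicate 1 (0.0495). The Pparg probe read below the floor in both groups, so no change of this factor can be read from it, and its call was lost without either berberine array. Of 21 measured members 12 were lower and 4 higher, a count that includes Pparg among the higher ones (14 and 5 adjusted over the list alone), and camera gave adjusted p = 0.00102 but adjusted p = 0.373 with an estimated correlation. Only 1 member, Stat5a, fell at least 8-fold, against 0.98 in matched random lists.

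**Figure D2:**
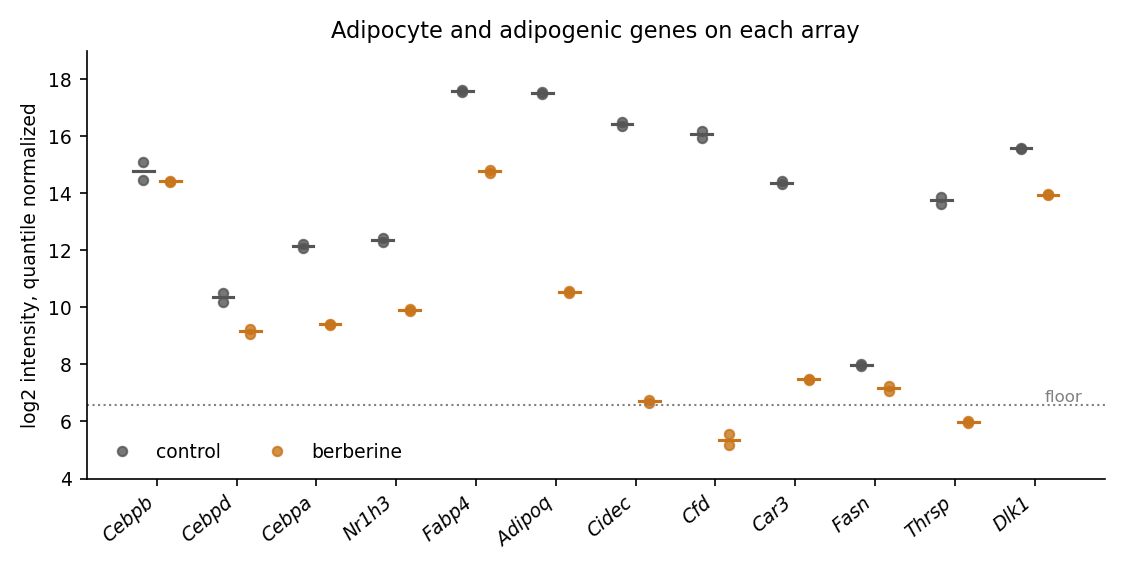
Quantile-normalized log2 intensity of 12 genes on each array (points), with the group mean as a bar, for 2 control and 2 berberine arrays, and the floor as a dotted line. Adipoq goes from 17.51 to 10.54 and Cfd from 16.07 to 5.36, below the floor, while Cebpb lies at 14.79 and 14.42.

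Genes of lipid and sterol synthesis were lower with berberine. Thrsp, a regulator of lipogenesis, fell at least 144-fold, Dgat1, an enzyme of triglyceride synthesis, at least 93.0-fold, Slc25a1, the mitochondrial citrate carrier, 13.5-fold and Pcx, pyruvate carboxylase, 2.65-fold. Fasn, fatty acid synthase, was dim and fell 1.77-fold (adjusted p = 0.00695), a call lost without either berberine array. In the fatty acid and triglyceride synthesis list 10 of 17 members fell and 2 rose (10 and 2 adjusted over the list alone), with camera adjusted p = 0.000768 and adjusted p = 0.504 with an estimated correlation. In the cholesterol list, Fdps, farnesyl diphosphate synthase, fell at least 61.6-fold, Pmvk 14.1-fold and Tm7sf2 2.74-fold, and Dhcr7 fell to 7.63 on the log2 scale (adjusted p = 0.000238), all enzymes of sterol synthesis. For Pmvk, the other probe above log2 10 in control fell as well, while the remaining probe, under the floor, had the opposite sign. In the cholesterol list 11 of 18 members fell and 1 rose (11 and 2 adjusted over the list alone), with camera adjusted p = 0.00102 and adjusted p = 0.373 with an estimated correlation. In each of these lists 3 members fell at least 8-fold, against 0.91 and 1.00 in matched random lists (permutation p = 0.058 and 0.070, not adjusted).

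Nuclear-encoded genes of oxidative phosphorylation were lower relative to other genes. The complex I subunits Ndufa8 and Ndufs3 fell 83.3-fold and 25.8-fold, the complex II subunit Sdhb fell 24.3-fold, and Atp5o, a subunit of ATP synthase, fell at least 18.9-fold. Of 37 members 20 fell, 2 rose and 15 did not pass (21 and 2 adjusted over the list alone). The median log2 change was -0.49, with camera adjusted p = 2.74e-06 and adjusted p = 0.373 with an estimated correlation. After arrays were centred on their median, the list's median was 0.0056, against 0.52 for all probes, and camera gave adjusted p = 0.00771. In this list 5 members fell at least 8-fold, against 2.45 in matched random lists, and the median did not lie apart from such lists (permutation adjusted p = 0.0641). Of 17 fatty acid oxidation genes 8 fell and 2 rose (8 and 3 adjusted over the list alone), among them Etfdh, an electron transfer enzyme (34.1-fold), and the acyl-CoA dehydrogenases Acads (19.5-fold) and Acadvl (2.85-fold), and Ppargc1b, a coactivator (2.33-fold). Its camera adjusted p of 0.0211 was lost without control replicate 2 (0.0822) and under other scalings (0.0873 to 0.102), its median of -0.31 turned to 0.055 after centring, and adjusted p was 0.504 with an estimated correlation. At least 8-fold falls were counted at 2 members, against 0.82 in matched random lists (permutation p = 0.197, not adjusted). The median did not lie apart from such lists (permutation adjusted p = 0.143).

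Lysosome and autophagy genes and glucocorticoid response genes were lower relative to other genes after quantile normalization. Ctsd, the protease cathepsin D, fell 50.4-fold, Wipi1, an autophagy protein, 15.8-fold, Sqstm1, an autophagy receptor, 15.1-fold and Hexa, a lysosomal hexosaminidase, 5.46-fold. Of 24 lysosome and autophagy genes 11 fell and 5 rose (13 and 5 adjusted over the list alone), with camera adjusted p = 0.00428 and adjusted p = 0.373 with an estimated correlation. Among glucocorticoid response genes, Sult1a1 fell 20.5-fold, Errfi1 6.73-fold, Nfkbia 3.99-fold and Hsd11b1, which regenerates active glucocorticoid, 3.24-fold, a call lost without berberine replicate 2 (adjusted p = 0.0517). There 7 of 17 fell and 2 rose (7 and 2 adjusted over the list alone), with camera adjusted p = 0.0337, which was 0.108 without control replicate 1, and adjusted p = 0.504 with an estimated correlation. Both calls were lost under the other scalings (0.0873 to 0.155). After centring the medians of -0.48 and -0.19 became 0.064 and 0.063, against 0.52 for all probes. At least 8-fold falls were counted at 3 and 2 members, against 1.56 and 1.09 in matched random lists (permutation p = 0.199 and 0.295, not adjusted). The medians did not lie apart from those of matched random lists (permutation adjusted p = 0.113 and 0.592).

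Further lists were described whatever their result, and none passed camera. Among cell cycle genes 21 of 36 rose and 8 fell (22 and 9 adjusted over the list alone), median log2 change 0.79 (1.31 after centring), camera adjusted p = 0.211. Prc1, a protein of cell division, rose 8.97-fold, while Birc5, a mitotic regulator, fell 10.8-fold (2.47-fold at a dimmer probe, with the remaining probe near the floor), Top2a, a DNA topoisomerase, at least 33.0-fold and Ccnb2, a mitotic cyclin, at least 8.66-fold. Among genes of the integrated stress response 20 of 32 rose and 6 fell (21 and 7 adjusted over the list alone), median 0.73 (1.15 after centring), camera adjusted p = 0.149, which was 0.0419 in the deposited values. Slc7a1, an amino acid transporter, rose 5.91-fold and Ppp1r15a, a phosphatase subunit, 4.04-fold, while Ddit3, a stress-induced transcription factor, fell 5.27-fold and Wars, a tRNA synthetase, 8.93-fold. Among inhibitors of adipogenesis 7 of 22 rose and 8 fell (7 and 8 adjusted over the list alone), camera adjusted p = 0.361, with a median of -0.022 that was 0.47 after centring. Gata3 rose 6.02-fold, Id2 and Id3 fell 5.26-fold and 4.88-fold, and Dlk1, a preadipocyte marker, fell 3.09-fold at its brighter probe, while the other probe changed by -0.20 on log2 and did not pass (adjusted p = 0.355). At least 8-fold falls were counted at 3 cell cycle, 1 stress response and 0 inhibitor members, against 1.48, 1.71 and 0.99 in matched random lists (permutation p = 0.184 for cell cycle, not adjusted).

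**Figure D3:**
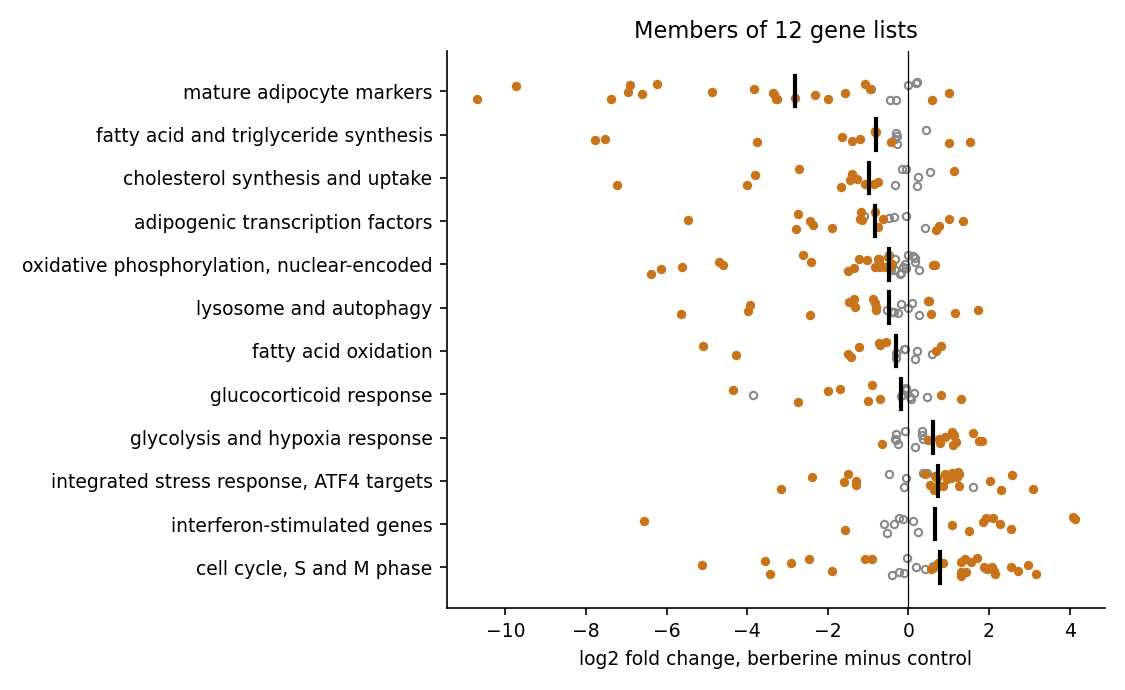
Log2 fold change of each measured member of 12 gene lists, filled where the adjusted p was under 0.05 and open where not, with the list's median as a black bar. The median of mature adipocyte markers lies at -2.82 and that of cell cycle genes at 0.79, and each list holds members on both sides of 0.

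The largest rises included Rsad2 and Ifi44, members of the interferon-stimulated list, which did not pass camera (adjusted p = 0.367). Rsad2, an antiviral gene, rose 17.5-fold and Ifi44 rose by 4.08 on the log2 scale. Celf1, an RNA-binding protein, rose at least 26.2-fold from below the floor, Car6 44.0-fold, Taf7l 37.8-fold, Cdsn 19.6-fold, Atp2a3 18.8-fold and Cox6a2 14.1-fold. Besides the adipocyte genes Cfd, Cidec and Thrsp, the largest falls were at Phlda3 (at least 394-fold), the matrix gene Fn1 (at least 326-fold), the proteasome subunit Psmb7 (at least 204-fold), Capns1 (274-fold) and Gstp1 (271-fold). Each of these falls rests on a single probe, with no other probe of the gene to check it. Of other proteasome subunits, single genes chosen after their values were seen and no test of the group, Psma6 fell 117-fold, Psmb9 rose 4.05-fold and Psmb5 was at 14.38 in control and 14.45 with berberine (adjusted p = 0.692). Lgals3, which encodes galectin-3, was 0.37 higher on log2, did not pass (adjusted p = 0.0597), passed with an intensity trend and robust prior (adjusted p = 0.0419) and was at -0.26 in the deposited values.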

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

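Scaling on the 75th percentile and the fit without probes that changed at least 8-fold were chosen after the data were seen; the other alternatives were fixed before. The number of probes past the threshold was 11838 (7164 higher, 4674 lower). It was 6687 in the deposited values (2396 higher), 12760 with the replicate block, 5806 with at least a 2-fold change added (2863 higher, 2943 lower) and 5887 at an unadjusted p under 0.05 with at least a 2-fold change (2922 higher, 2965 lower). Leaving out each array in turn gave 4339 to 10772 probes, 1867 to 6545 higher and 2472 to 4227 lower, with the lone array assumed to vary like the other group. Without berberine replicate 1 or 2, 4278 and 4523 of the calls were shared with the full set, and the cause was not tested. The deposited values shared 6205 calls with it, centring on the median 10235 and the 75th percentile 8234. Of the 8 gene lists past camera, 5 passed after centring, 5 after scaling on the 75th percentile and 0 with an estimated correlation. That correlation was below 0 for mature adipocyte markers (-0.015), adipogenic transcription factors (-0.024), cholesterol (-0.033), lysosome and autophagy (-0.014) and glucocorticoid response (-0.029). Their losses come from the 2 degrees of freedom, not from the estimated correlation. For the other lists it was 0.044 to 0.21. With so few degrees of freedom a miss decides little: mature adipocyte markers had an unadjusted camera p of 0.0165. In all 3 scalings other than quantile normalization, the lists that no longer passed were fatty acid oxidation, glucocorticoid response and lysosome and autophagy. Glucocorticoid response also missed the threshold without control replicate 1 (adjusted p = 0.108), with probes of a gene averaged (0.0505) and without probes that changed at least 8-fold (0.0605). Fatty acid oxidation missed it without control replicate 2 (0.0822) and without probes that changed at least 8-fold (0.0695). Lists that passed under an alternative alone were glycolysis (0.0364), the integrated stress response (0.0419) and interferon-stimulated genes (0.0419) in the deposited values, p53 targets (0.00246) and galectins (0.000923) with the replicate block, and the integrated stress response with camera on ranks (0.0364). Among the 65 genes named by the rule, which were run under the scalings, the block, the trend, each array left out, log2(value + 16) and averaging, 0 calls reversed; genes named outside the rule were not run. The sizes of changes moved with the scaling. Log2 changes after quantile normalization were -1.40 for Pcx, -1.51 for Acadvl and -1.63 for Dlk1. After centring on the median they were -0.68, -0.77 and -0.87. Signal over background limits the dim probes: 5514 probes lay below an intensity of 95.8 in both groups.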

Other observations

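The comparisons with random lists matched on control level, the pairs of probes and the tests of explanations below were chosen after the results were seen, as were the genes named here, except where the text above names them. Interferon-stimulated genes were more often higher than lower with berberine, as were all genes (5321 higher and 3219 lower of 17734), without passing as a list. Of 18 measured, 9 rose and 2 fell (9 and 3 adjusted over the list alone), median log2 change 0.66 (1.33 after centring and 1.07 after scaling on the 75th percentile), camera adjusted p = 0.367. Rsad2 and Ifi44, named above, are among those that rose. Irf7, a transcription factor of the interferon response, rose 4.84-fold, Ifit1 5.82-fold and Mx2 4.31-fold, while Ifi35 fell 94.3-fold. Among 22 cytokine and chemokine genes 10 rose and 5 fell (10 and 6 adjusted over the list alone, camera adjusted p = 0.938), with Il6 up 5.20-fold, Ccl5 up 3.94-fold and Ccl2 down 5.49-fold. Glycolysis and hypoxia response genes had 12 of 22 higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.106), among them Slc2a1, a glucose transporter, up 3.35-fold and Pdk1, a kinase that inhibits pyruvate dehydrogenase, up 2.17-fold. In the actin list 7 of 14 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.447), with Acta2 up 2.32-fold and Cnn2 down 9.16-fold. Among 17 genes of the insulin and IGF pathway 4 rose and 7 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.149, median -0.13, and 0.29 after centring), with Akt1 down 6.01-fold, Igf2 9.36-fold and Irs1 3.35-fold. Among 16 cAMP response genes 6 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.846), with Ptgs2 up 8.85-fold and Rgs2 down 6.24-fold.

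Other lists had members on both sides, and camera did not pass. Of 31 collagen and matrix genes 12 rose and 14 fell (13 and 14 adjusted over the list alone, camera adjusted p = 0.149), with Lum down 8.41-fold and Timp3 up 6.78-fold. Of 17 p53 targets 6 rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.195), with Fas down 39.9-fold and Bbc3 up 4.76-fold. Of these targets 3 fell at least 8-fold against 0.97 in matched random lists (permutation p = 0.0684, not adjusted). Of 17 NRF2 targets 5 rose and 5 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.442), with Nqo1 down 30.1-fold and Hmox1 up 2.51-fold. Of 9 galectins 2 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.210), with Lgals9 down 69.0-fold and Lgals12 24.2-fold, and 3 members fell at least 8-fold against 0.48 in matched random lists (permutation p = 0.0104, not adjusted). Counts of members higher and lower, the same adjusted over the list alone, and the camera adjusted p were 3 and 4 (4 and 4, 0.563) for endoplasmic reticulum chaperones, 3 and 1 (4 and 1, 0.709) for heat shock proteins and 3 and 6 (3 and 6, 0.221) for the basement membrane. They were 2 and 1 (2 and 2, 0.846) for aryl hydrocarbon receptor targets, 2 and 1 (2 and 1, 0.846) for subunits of AMP-activated protein kinase, 6 and 7 (7 and 8, 0.483) for ribosomal proteins and 1 and 2 (1 and 2, 0.442) for reference genes. No mitochondrially encoded transcript was measured under a name. The median was above 0 and the mean below it for chaperones (0.17 and -0.54), NRF2 targets (0.030 and -0.31), aryl hydrocarbon receptor targets (0.44 and -0.57), kinase subunits (0.098 and -0.16) and ribosomal proteins (0.23 and -0.31), and each of these medians was higher after centring. Medians of collagens, p53 targets, galectins, the basement membrane and reference genes were below 0 and turned above 0 after centring, and those of NRF2 targets, aryl hydrocarbon receptor targets and ribosomal proteins were below 0 in the deposited values. Centring shifts all genes alike, and the median change of all probes was 0.52 after it. These turns therefore reflect the scaling, and the medians that turned still lay below 0.52.

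Markers of other cell types were tested as lists of their own, and none passed camera. Members higher and lower, the same adjusted over the list alone, and camera adjusted p were 5 and 2 (5 and 2, 0.687) of 11 for macrophages, 4 and 0 (4 and 0, 0.438) of 9 for endothelial cells and 4 and 1 (5 and 1, 0.438) of 8 for osteoblasts. They were 1 and 3 (1 and 3, 0.438) of 8 for chondrocytes, 1 and 1 (1 and 1, 0.486) of 7 for epithelial cells, 1 and 2 (1 and 1, 0.538) of 8 for brown adipocytes and 3 and 3 (3 and 3, 0.687) of 11 for fibroblasts and preadipocytes. Of 4 skeletal muscle markers 2 were higher and 0 lower, too few for a test. The median and mean differed in sign for brown adipocytes (0.068 and -0.50) and fibroblasts (0.21 and -0.010).

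Against random lists matched on control level, the median lay apart with adjusted p under 0.05 for mature adipocyte markers and the integrated stress response (0.0056 each), transcription factors and cell cycle genes (0.0112 each), cholesterol (0.0134), fatty acid and triglyceride synthesis (0.0289) and glycolysis (0.0472). It did not for actin (0.0539), oxidative phosphorylation (0.0641), interferon-stimulated genes (0.0986), lysosome and autophagy (0.113), cytokines (0.113), fatty acid oxidation (0.143) or glucocorticoid response (0.592). Glycolysis and actin lie near the threshold, where another random draw can change the side.

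Probes bright in control often fell at least 8-fold with berberine while another probe of the same gene did not. A fall of the whole transcript is argued against as the general account, since the other probe fell at least 2-fold in 31.5% of 111 genes (exact 95% interval 23.0% to 41.0%), against 21.8% of all bright probes. Normalization between arrays as done here is argued against as well, since 99.7% of these probes were down at least 8-fold in the deposited values. The array medians differed by only 0.84 on log2, so that outcome was nearly fixed in advance. Any scaling before deposit is not known. A single series of probe identifiers is argued against too, since the lowest share among the 3 series was 5.22%. The share differed between series, at 9.91% (exact 95% interval 8.94% to 10.9%) in the highest. Changes in part of a transcript, loss of signal at single probes on the berberine arrays and excess signal on the control arrays stay open and were not tested, because probe sequences and positions were not used here.

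Lower mature adipocyte markers are not accounted for by losses at the rate of all probes. The median differed from random lists matched on control level (permutation of genes within level bins, adjusted p = 0.0056), and 13 members fell at least 8-fold against 1.41 in such lists (p = 0.0001, the smallest these draws can give). The count was tried first and the median replaced it after its value was seen. The median was below 0 in all 4 scalings, with camera adjusted p of at most 2.26e-10 (after quantile normalization, adjusted p = 0.373 with an estimated correlation). Settings other than quantile normalization differ by a shift common to all genes, with list medians of -2.76, -2.19 and -2.45. The median change of all probes was only -0.05 to 0.52, so this outcome was nearly fixed in advance. A common shift of that size is argued against, and other effects of scaling were not tested. An effect of berberine on these genes stays open. The list and its camera test were fixed before the data were examined, but the comparison with random lists was not. The labels do not say whether the samples came from separate cultures or whether the groups were handled apart.

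Lower oxidative phosphorylation genes may rest partly on single probes and on scaling. The median did not differ from matched random lists past the threshold (permutation adjusted p = 0.0641), and 5 members fell at least 8-fold against 2.45 in such lists (p = 0.0912), so losses at the rate of all probes and a shared fall cannot be told apart with 37 members. The median test replaced the count after its value was seen, and the pattern itself replaced cell cycle genes, which had been planned. The median turned above 0 after centring (0.0056, against 0.52 for all probes), so a fall in level depends on the scaling. Camera placed the list below other genes in all 4 scalings, with adjusted p of at most 0.00771 (after quantile normalization, adjusted p = 0.373 with an estimated correlation). Settings other than quantile normalization keep the order of fold changes, so camera had little room to differ among them. A biological fall of these genes with berberine stays open.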
